A study of Drosophila melanogaster with 6 samples.

How the data were processed

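RNA was measured in eye discs of late larvae of the fruit fly in 6 groups, made of 2 genotypes and 3 foods. Per the labels, each group holds 3 total-RNA libraries that were depleted of ribosomal RNA and kept strand information, made from 30 pairs of discs and read as 50 bp pairs. Per the submitters' processing notes, TopHat, Bowtie, Cufflinks, Cuffdiff 2.1.1 and the dm6 genome build were used; the roles and settings of these tools are not given in the sources used here.

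The authors deposited 1 gene table of all 15 pairwise comparisons of the 6 groups, with 15904 gene rows in each. It gives an FPKM value (fragments scaled to transcript length and to the mapped fragments of the library) per group, which the authors made from the 3 libraries of that group, per the file headers. The authors also deposited a score for each row and comparison, the Cuffdiff test statistic, and a p-value and a q-value. The deposited p-values are whole multiples of 5e-05. The deposited q-values equal a Benjamini-Hochberg adjustment over the tested rows of all 15 comparisons together, with a largest difference of 5.28e-07. Between 10344 and 10639 rows per comparison had a test. Values of single libraries were not used here, so the spread between libraries enters only through the authors' own test, and depth per library is unknown. The low FPKM values showed no steps of whole reads: at most 4.28% of low-value ratios fell in one step of 0.02 on the log2 scale. The labels do not say whether the 3 libraries of a group came from separate cultures of larvae, so the p-values measure the spread between these libraries, which may be partly technical.

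The table had passed through a spreadsheet. Rows were matched by position, 5 gene symbols that had become dates were restored from their genome positions, and fold changes were recomputed from the FPKM values in place of the damaged log2 column. Symbols were compared with a reference annotation of the BDGP6 assembly, the same build, in which 14862 of 15267 single symbols (97.3%) overlapped the deposited position. Positions printed for genes come from that annotation. Another 637 rows hold several genes whose values cannot be separated. The gene hid stands in the table under its older symbol W.

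A gene row was called where the deposited q was at most 0.05, as written before the data were examined. Fold changes are plain FPKM ratios, and none is given against a group listed at 0. Gene lists and the ranking of named genes used log2(FPKM + 1), a scale that understates the change of low genes. The standard error (SE) of a log2 ratio was taken as its absolute size divided by the absolute deposited statistic. The deposited p-values are smaller than a normal reading of that statistic gives: the median ratio of the statistic to the normal z of its p-value was 0.576, and the median SE was 0.51 from the statistic and 0.30 when rescaled to the p-values. Printed SEs are the larger, unscaled ones.

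A total of 39 gene lists was fixed before the data were examined, and 38 have members in the table. For each list and comparison the members called higher and lower were counted, over all genes and with the deposited p adjusted over the list alone. The list's median was placed among 10000 random lists of the same size matched on mean expression, and a list stood apart below the percentile 2.5 or above 97.5. This percentile describes these libraries and is not a test across replicates. The named genes followed a rule also fixed beforehand: in each main comparison the 8 called genes with the largest rise and the 8 with the largest fall on the log2(FPKM + 1) scale (single symbols, no small or unnamed RNA, FPKM of at least 1 in the higher group), up to 4 called members per list, and always w, rpr, hid, grim, gl, nej, Hrb87F, roX1 and roX2. A choice from these genes is described.

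Whether a supplement's effect differed between genotypes was tested on the difference of the 2 log2 ratios over the root of their summed squared SEs, with a normal approximation and Benjamini-Hochberg adjustment. Overlaps of calls between comparisons that share a group were set beside the overlap of independent lists and beside 100 simulated sets in which no gene changed. Correlations used 6647 single-gene rows with FPKM of at least 1 and a rescaled SE of at most 1, a restriction chosen after the data were seen. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots matplotlib 3.10.9.

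The methods were tested on simulated data. For Rasa-Sindoor, the test of the difference between genotypes found 55% of 100 rows changed by 3 on the log2 scale and 0% of 100 rows changed by 1, among 10099 rows, and for Amalaki Rasayana it found 63% and 1% among 9978 rows. With rescaled SEs, which the simulated noise matches by construction, the shares were 77% and 17% for Rasa-Sindoor and 76% and 15% for Amalaki Rasayana. Simulated lists of 20 rows stood apart in 3% of cases with no shift and in 100% with a shift of 0.5 on the log2 scale, in the comparison of the genotypes on normal food over 10639 rows. Removing a simulated length trend lowered its slope from 0.31 to 0.02 in the comparison of Rasa-Sindoor with normal food in the polyQ line, over 8799 rows.

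Alternatives tried were a q of at most 0.01, adjustment within each comparison, an FPKM minimum of 1, rows of single named genes, a minimum change, centring on the median, and other pseudocounts. After the data were seen, rescaled SEs, removal of a trend on transcript length, matching of lists on transcript length and removal of markers of other tissues were added. Lists matched on transcript length as well were drawn only from single named genes outside the list, without small RNAs. Lists matched on expression alone were drawn from all tested rows, with small RNAs, multi-gene rows and the list's own members. A list's percentiles under these matchings thus differ in more than transcript length. No q was computed after removal of the length trend. A gene was then still called where its ratio over its rescaled SE was beyond 3.32, the normal z of the largest called p. Genes that could be corrected were called single genes with a known length that also passed this bound before the removal. No count model was used, because the table holds no counts.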

Results

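The data describe the eye discs of fruit fly larvae, the larval tissue that becomes the adult eye and antenna. One genotype carried GMR-GAL4 and UAS-127Q, which together express a protein with a long polyglutamine tract in the differentiating cells of the eye disc (polyQ line, PQ), and the other was the wild-type strain Oregon R+ (WT). Larvae ate normal food (NF) or food with 1 of 2 traditional Ayurvedic preparations, Amalaki Rasayana (AR), made from the amla fruit, or Rasa-Sindoor (RS), made from mercury and sulphur. Each of the 6 groups, written as genotype and food (PQ_NF, WT_RS), has 1 deposited FPKM value per gene from 3 libraries, 18 libraries in all. Between 8767 (WT_AR) and 9100 (WT_NF) rows reached an FPKM of 1. Small and unnamed non-coding RNAs held 65.1% of the summed FPKM in WT_AR and between 72.8% and 79.5% in the other 5 groups. All FPKM values are the authors' pooled group values, and SEs are those of log2 ratios. The polyQ line and the wild type also differ in strain, so a difference between them covers both the transgenes and the genetic background.

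The comparison of PQ_NF with WT_NF asks how the polyQ line differed from wild type on normal food. Steroid hormone genes were higher in the polyQ line: spok (chromosome 3R, 3322810 to 3354486) had 55.4 FPKM in PQ_NF and 7.43 in WT_NF (log2 ratio 2.90, SE 0.45), and nvd (chromosome 3L, 24324866 to 24401655) had 14.9 and 1.43 (3.38, SE 0.55). Both encode enzymes of ecdysone synthesis in the ring gland, an organ apart from the disc. Salivary glue genes were lower in the polyQ line. Sgs7 (chromosome 3L, 11509861 to 11510247) had 38.7 FPKM against 720 (−4.22, SE 0.64), and Sgs3, Sgs5 and Sgs8 had 8.69, 25.7 and 5.03 against 74.3, 195 and 68.9. The receptor kinase gene sev (chromosome X, 11071441 to 11086299), which specifies the R7 photoreceptor, was at 5.10 FPKM in PQ_NF and 21.7 in WT_NF (−2.09, SE 0.39; q = 0.00541 in the authors' deposited table). In all, 134 rows were called higher and 199 lower of 10639 tested.

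Among the chaperones, 3 of 23 tested members were called higher in PQ_NF and 1 lower. Hsp70Bb rose from 0.374 to 5.86 FPKM (3.97, SE 0.66), Hsp68 from 3.12 to 9.95 (1.67, SE 0.66) and the Hsp40 gene DnaJ-1 from 25.9 to 52.6 (1.02, SE 0.37), while the mitochondrial chaperonin gene Hsp60 fell from 70.1 to 30.3 (−1.21, SE 0.38). Adjusted over the list alone, 4 were higher and 1 lower. Hsp70Bb has near-identical copies, so its reads may be shared and its value is uncertain. Of 76 cytosolic ribosomal protein genes, 5 were called higher and 1 lower (16 and 5 adjusted over the list alone). Their median was 0.39 on the log2(FPKM + 1) scale, at the percentile 99.9 of lists matched on expression. It lay at 60.6 of lists matched on transcript length as well, a matching chosen after the data were seen and drawn from another pool of rows. RpL32 had 1313 FPKM against 613 (1.10, SE 0.44), and RpS19a went the other way with 252 against 507 (−1.01, SE 0.42). All 12 glycolysis genes lay lower in PQ_NF (median −0.41, percentile 0.02), and 2 of them were called, Eno with 60.1 FPKM against 114 and the lactate dehydrogenase gene ImpL3 with 2.27 against 5.00 (3 adjusted over the list alone). Nuclear genes of the respiratory chain went both ways, with 2 called higher and 4 lower of 67; the median of −0.03 over 66 with a known length lay below lists matched on length as well (percentile 0, lists from 0.14 to 0.41). The lower ones included CG3731, a complex III core subunit, at 18.2 FPKM against 51.7 (−1.51, SE 0.38), and the complex I subunit ND75 at 6.70 against 17.9 (−1.42, SE 0.39).

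The cytochrome P450 genes had 4 members called lower of 41, among them Cyp9c1 with 1.63 FPKM against 6.69. The antifungal peptide gene Drs rose from 2.29 to 10.7 FPKM (2.22, SE 0.78; q = 0.0165 in the authors' deposited table), and the iron carrier gene Tsf1 fell from 7.35 to 1.96. No gene of retinal determination was called among 16, and their median was −0.31 (percentile 0.06). Of 21 photoreceptor differentiation genes, sev alone was called (1 higher and 3 lower adjusted over the list alone), with a list median of −0.22 (percentile 0.49). Genes called higher had shorter transcripts than those called lower (medians of 1326 and 2342 bases). With a smooth trend on length removed, 74 of 104 higher and 152 of 171 lower genes that could be corrected were still called by the z bound. The 30 and 19 that were not went from median ratios of 0.93 to 0.72 and from −0.83 to −0.74, with median rescaled SEs of 0.26 and 0.23. The cell death genes rpr (10.9 against 7.78 FPKM), hid (22.9 against 21.6) and grim (0.774 against 0.599) were not called, nor were gl, the factor that drives GMR (26.6 against 37.4), nej, which encodes the acetyltransferase CBP (15.9 against 17.8), or Hrb87F, an hnRNP (86.9 against 85.1). The row that joins w with CG32795 had 35.3 against 15.9 FPKM and was not called. Markers of other tissues moved beside these genes. Called lower were 5 of 7 salivary gland, 2 of 4 tracheal and 2 of 7 antennal markers. Called higher were 2 of 6 ring gland and 3 of 13 muscle markers. Haemocyte markers had a median of −0.27 (percentile 3.35), and cuticle protein genes stood apart on the lower side (percentile 0.81). Brain markers had a median of 0.22 (percentile 96.8, and 99.7 of lists matched on length as well). Without these markers and those of fat body and glia, 128 rows were higher and 188 lower.

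**Figure D1:**
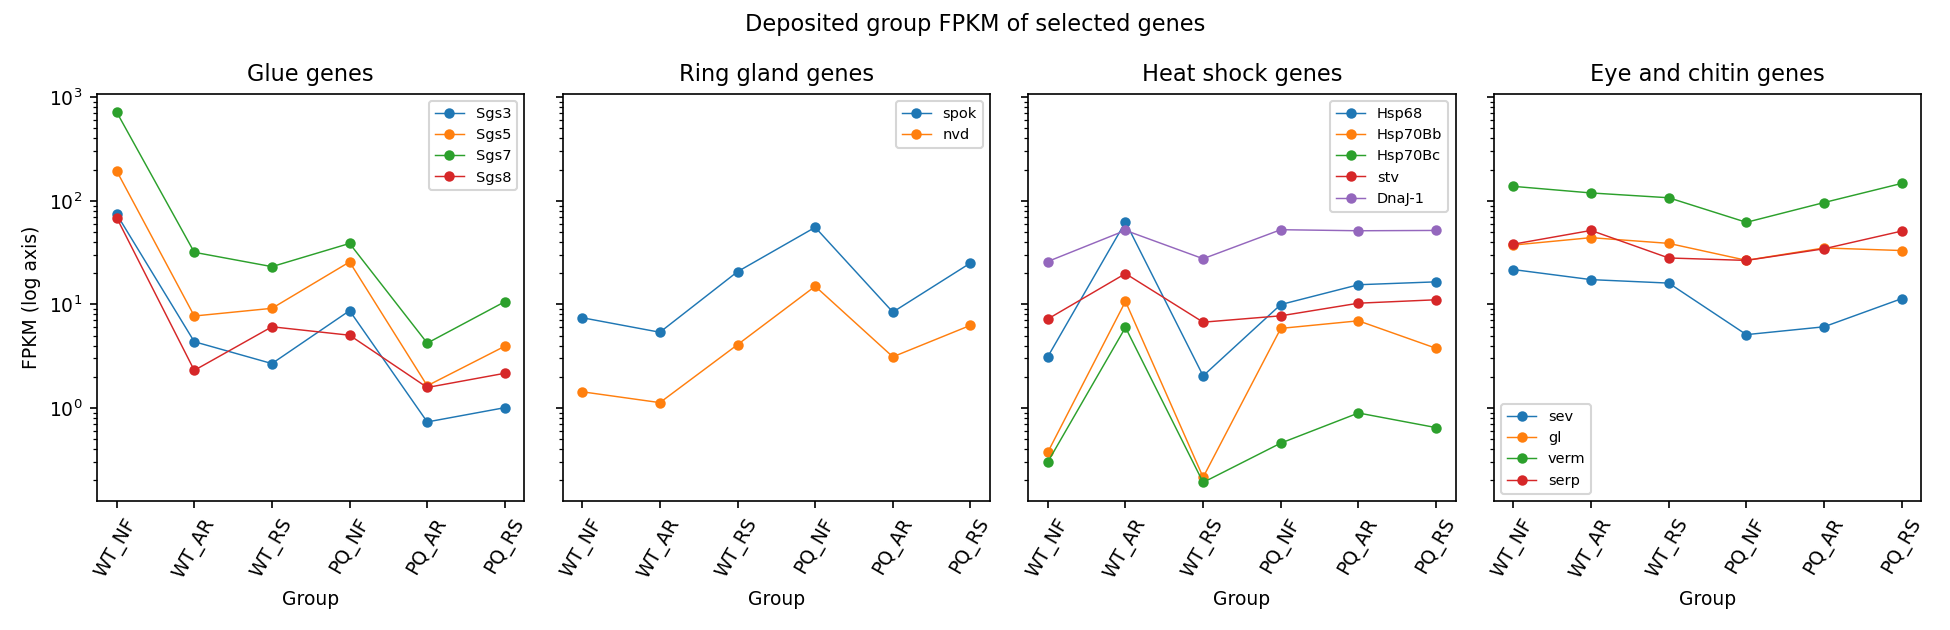
Deposited FPKM (log axis) of named genes in the 6 groups, 1 pooled value per point from 3 libraries, with lines that only join points of a gene. Sgs7 stands at 720 FPKM in WT_NF and between 4.22 and 38.7 in the other 5 groups, spok peaks at 55.4 in PQ_NF, and Hsp68 peaks at 62.5 in WT_AR.

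Amalaki Rasayana in the polyQ line was assessed as PQ_AR against PQ_NF. Glue and ring gland genes were among those that fell most. Sgs5 fell from 25.7 to 1.64 FPKM (−3.97, SE 0.73), Sgs7 from 38.7 to 4.22 (−3.20, SE 0.73), spok from 55.4 to 8.42 (−2.72, SE 0.43) and nvd from 14.9 to 3.11 (−2.26, SE 0.47). Eig71Ee, an ecdysone-induced gene, fell from 15.1 to 0.649 FPKM (−4.54, SE 0.69) and the odorant-binding protein gene Obp56d from 12.4 to 0.753 (−4.05, SE 0.99). The 3 named genes that rose were the homeobox gene E5 (5.02 against 2.48 FPKM), CG3731 (31.8 against 18.2) and Hsp60 (50.7 against 30.3; q = 0.0489 in the authors' deposited table). In all 4 rows were called higher and 22 lower of 10369, and the 4 higher ones were no longer called with a q of at most 0.01 or with adjustment within this comparison. An unadjusted p below 0.05 in the authors' deposited table was reached by 267 rows. Unchanged groups would give more such rows if p is uniform. Without markers of other tissues 4 were higher and 16 lower.

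Several lists stood apart on Amalaki Rasayana in the polyQ line with few or no called members. The medians were 0.25 for retinal determination (0 of 16 called, 15 above 0), 0.25 for glycolysis (0 of 12 called), −0.25 for glutathione S-transferases (1 of 27 called, GstE14, at 0.512 FPKM against 3.28) and −0.14 for proteasome subunits (0 of 30 called), which with lists matched on length as well no longer stood apart (percentile 4.70). Markers of other tissues stood apart as well, with medians of −0.28 for muscle (percentile 0.02, 11 of 12 below 0, 1 called lower), −0.17 for haemocytes (percentile 1.61, 0 of 10 called) and 0.35 for trachea (percentile 99.7, 0 of 4 called). In PQ_NF against WT_NF the medians of retinal determination, glycolysis, proteasome, muscle and trachea had the opposite sign. Those of glutathione S-transferases and haemocytes had the same sign. Both comparisons use PQ_NF, so a chance deviation there shifts a list in opposite directions without any effect of the supplement. Of the genes named in every comparison, rpr had 7.50 FPKM against 10.9, hid 25.3 against 22.9, gl 35.0 against 26.6 and nej 16.5 against 15.9, and none of these was called.

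Rasa-Sindoor in the polyQ line, PQ_RS against PQ_NF, gave 90 rows called higher and 166 lower of 10458. The chitin deacetylase genes verm and serp rose from 62.0 to 147 FPKM (1.25, SE 0.41) and from 26.6 to 51.0 (0.94, SE 0.38). With obst-A (132 against 77.0 FPKM) they made up 3 of the 4 tested tracheal markers. Hsp60 rose to 65.3 FPKM from 30.3 (1.11, SE 0.38), CG3731 to 41.2 from 18.2 (1.18, SE 0.39) and ND75 to 12.4 from 6.70 (0.89, SE 0.40). Nuclear genes of the respiratory chain as a list went both ways, with 3 called higher and 2 lower of 67 (3 and 6 adjusted over the list alone) and a median of 0.00 (percentile 80.4, and 100 of lists matched on length as well); the lower ones were CG3560 at 46.2 FPKM against 92.6 and CG3214 at 41.0 against 77.7. The gene sev rose from 5.10 to 11.3 FPKM (1.15, SE 0.39). The cell death gene rpr fell from 10.9 to 5.04 FPKM (−1.12, SE 0.51; q = 0.0225 in the authors' deposited table), while hid (24.4 against 22.9) and grim (0.321 against 0.774) were not called.

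Of 76 cytosolic ribosomal protein genes, 6 were called lower on Rasa-Sindoor and none higher (5 higher and 22 lower adjusted over the list alone), with a median of −0.34 (percentile 0.01 of lists matched on expression). Matched on transcript length as well, the list did not lie below other genes (75 genes, median −0.36, percentile 83.7, matched lists from −0.55 to −0.29). RpL36A fell from 1643 to 713 FPKM (−1.20, SE 0.46) and RpS23 from 2380 to 1074 (−1.15, SE 0.53). The mitochondrial ribosomal protein genes had 3 members lower of 70 (0 higher and 6 lower adjusted over the list alone; median −0.30, percentile 0, and 80.1 of lists matched on length as well). Proteasome genes had 2 lower of 30, Prosalpha6 at 64.8 FPKM against 117 and Rpn5 at 39.7 against 65.8. The JNK gene bsk had 31.3 FPKM against 53, and Rheb, an activator of TOR kinase, 18.8 against 32.9. Glycolysis genes lay higher (median 0.44, percentile 100, 0 of 12 called and 2 higher adjusted over the list alone), as did those of retinal determination (median 0.29, percentile 99.5, 0 of 16 called and 3 higher adjusted over the list alone). Antennal disc markers (median 0.34, percentile 97.8) and glia markers (median 0.26, percentile 98) lay higher too, while muscle, haemocyte and fat body markers did not stand apart. With lists matched on length as well, glia markers no longer stood apart (percentile 97.45). Metallothionein and metal handling genes lay higher under both matchings (median 0.35 over 10 genes with a known length, percentiles 99.6 and 99.7). Their median in PQ_NF against WT_NF was −0.15 (percentile 18.8). Glycolysis, retinal determination and antennal lists lay lower in PQ_NF against WT_NF, which shares PQ_NF, so part of these medians may come from that group. The same holds for the tracheal list, with medians of −0.63 in PQ_NF against WT_NF and 0.84 in PQ_RS against PQ_NF. Of 33 cell cycle genes, Mcm3 was called higher at 28.7 FPKM against 14.5 and cdc2 lower at 46.3 against 80.6. Sgs3, Sgs5, Sgs7, spok and nvd fell here as well, spok to 25.1 FPKM (−1.14, SE 0.49). The genes called lower had shorter transcripts, with a median of 901 bases against 2539 for those called higher and 1947 for those not called. After a smooth trend of the ratio on length was removed, 64 of the 143 lower genes that could be corrected were still called by the z bound. Of the higher ones 53 of 80 were. The 79 and 27 that were not went from median ratios of −0.96 to −0.68 and from 0.83 to 0.69, with median rescaled SEs of 0.25 and 0.23.

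For Amalaki Rasayana in wild type, heat shock genes were higher in WT_AR than in WT_NF. WT_AR also held the lowest share of small and unnamed non-coding RNAs of the 6 groups (65.1% of the summed FPKM). Causes other than the supplement were not tested. Hsp68 (chromosome 3R, 24055080 to 24057310) rose from 3.12 to 62.5 FPKM (4.32, SE 0.66), Hsp70Bb from 0.374 to 10.7 (4.84, SE 0.67), Hsp70Bc from 0.30 to 5.99 (4.32, SE 0.74) and stv, a BAG-family co-chaperone gene, from 7.22 to 19.8 (1.46, SE 0.41). In the chaperone list 7 of 24 members were called higher and none lower (10 and 0 adjusted over the list alone), with a median of 0.36 (percentile 100). Hsp70Bb and Hsp70Bc are near-identical copies, so how the authors' counting split their reads is uncertain. Glue genes fell, with Sgs5 at 7.71 FPKM against 195 and Sgs7 at 31.8 against 720 (−4.50, SE 0.63). The prophenoloxidase genes PPO1 and PPO2, markers of crystal cells, fell from 10.2 to 4.90 FPKM and from 10.7 to 4.91. Small nuclear and nucleolar RNAs had a median of −0.59 (percentile 0), with 3 of 265 called lower. In all 19 rows were higher and 64 lower of 10485. Adjustment within this comparison left 42 lower, and without markers of other tissues 18 were higher and 55 lower.

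Rasa-Sindoor in wild type, WT_RS against WT_NF, gave few called genes. Glue genes fell, with Sgs7 at 23.1 FPKM against 720 (−4.96, SE 0.65) and Sgs3 at 2.68 against 74.3, and Eig71Ee fell from 36.8 to 2.80. Sgs7 lay between 4.22 and 38.7 FPKM in all groups other than WT_NF, so its falls on both supplements in wild type share that 1 high group. Whether the groups differed in the amount of salivary gland tissue was not tested. The ring gland genes spok and nvd rose from 7.43 to 20.7 FPKM (1.48, SE 0.46) and from 1.43 to 4.08 (1.51, SE 0.59). ND75 fell from 17.9 to 9.74 FPKM (−0.88, SE 0.39), with SdhC, a complex II subunit, at 19.3 against 34.5. Haemocyte markers had a median of −0.18 (percentile 2.36), with 1 of 10 called lower, PPO2 at 5.59 FPKM against 10.7. The antimicrobial gene CecC was listed at 0 in WT_NF and had 1.10 FPKM in WT_RS. Respiratory chain genes had a median of −0.30 (2 of 68 called lower, percentile 0), cytosolic ribosomal protein genes −0.27 (0 of 75 called) and proteasome genes −0.25 (1 of 30 called lower, Rpt6, at 20.7 FPKM against 34.8). In all 16 rows were higher and 20 lower of 10608, with 427 rows at an unadjusted p below 0.05 in the authors' deposited table. That is fewer rows than such a bound gives in unchanged groups if p is uniform. Adjustment within this comparison left 8 higher and 12 lower.

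Across these 5 comparisons 10 lists had no called member. They included the hnRNP genes (12 tested, medians −0.04 in PQ_NF against WT_NF, 0.16 and 0.11 for Amalaki Rasayana and Rasa-Sindoor in the polyQ line), the autophagy genes (21 tested, medians 0.01, 0.03 and 0.07 in the same order), phototransduction and fat body markers. In PQ_AR against PQ_NF the hnRNP list lay at the percentile 97.2, and at 98.9 of lists matched on length as well. Of the lists that stood apart when matched on expression, 10 of 13 (PQ_NF against WT_NF), 10 of 13 (PQ_AR against PQ_NF), 6 of 12 (PQ_RS against PQ_NF), 12 of 15 (WT_AR against WT_NF) and 10 of 11 (WT_RS against WT_NF) still did so when matched on transcript length as well. The random lists of these matchings came from different pools of rows, so the losses cannot be put down to length alone. Neither roX1 nor roX2, the RNAs of X dosage compensation, was called.

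The remaining pairs of groups compared the supplements with each other and the genotypes on supplemented food. PQ_RS against PQ_AR gave 20 rows higher and 42 lower of 10354, with sev the called member of the photoreceptor list and a median of −0.18 for mitochondrial ribosomal protein genes (1 of 70 called lower). WT_RS against WT_AR gave 82 higher and 100 lower of 10449. In this pair 15 of 75 cytosolic ribosomal protein genes and 7 of 24 chaperone genes were called lower, 9 of 274 small nuclear and nucleolar RNAs higher and 2 of 6 ring gland markers higher. PQ_AR against WT_AR gave 107 higher and 99 lower of 10344, with 4 of 24 chaperone genes and 3 of 7 salivary gland markers lower. PQ_RS against WT_RS gave 77 higher and 75 lower of 10559, with 3 of 23 chaperone genes and 3 of 75 cytosolic ribosomal protein genes higher.

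The genotypes differed the same way on all 3 foods at 52 rows, 24 higher and 28 lower in the polyQ line. Independent lists of these sizes would share 0.00961 and 0.0128 rows. The 3 comparisons share no group, and a difference between the strains recurs in each of them. The nicotinic receptor gene nAChRalpha6 had between 3.18 and 4.04 FPKM in the polyQ groups and between 0.0870 and 0.158 in wild type, and the serpin gene Spn47C between 7.38 and 8.64 against 0.459 to 0.676. CG33766, CG33768, CG33770 and CG33771 were listed at 0 in the 3 polyQ groups, and CG33766 had between 2.09 and 4.74 FPKM in wild type. snRNA:U2:34ABa, which has near-identical copies and is uncertain for that reason, had 14.9 FPKM in PQ_NF and 2551 in WT_NF. The P450 genes Cyp6a17, Cyp6a23 and Cyp9c1 were lower in the polyQ line on each food. These genes other than Spn47C, CG33766, snRNA:U2:34ABa and the P450 genes were chosen after their values were seen.

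Whether a supplement acted differently in the 2 genotypes was tested on the difference of the log2 ratios. For Amalaki Rasayana the difference passed for 6 of 9991 rows. Hsp70Bb had a log2 ratio of 0.24 in the polyQ line and 4.84 in wild type (difference −4.59, SE 0.79, adjusted p = 1.12e-05 by a normal test on the SEs from the authors' deposited table, with Benjamini-Hochberg adjustment), and Hsp68 had 0.64 and 4.32 (−3.69, SE 0.82, adjusted p = 0.0103 by the same test). The other 4 were small RNAs whose deposited p contradicts their statistic. For Rasa-Sindoor it passed for 7 of 10115 rows, 6 of them such small RNAs and the other a row that joins CG3860 with mir-1009. The ring gland gene spok fell on Rasa-Sindoor in the polyQ line and rose in wild type (difference −2.62, SE 0.67, adjusted p = 0.128 by the same test on SEs from the authors' deposited table). Whether the groups differed in the amount of ring gland tissue was not tested. With SEs rescaled to the deposited p, an alternative chosen after seeing the data, 22 and 97 rows passed, and without the contradictory rows 16 and 80. For Rasa-Sindoor the 97 include spok, at an adjusted p of 1.90e-08 by that test on rescaled SEs from the authors' deposited table, and nvd (difference −2.76) at 5.28e-07, where the SEs of the authors' deposited table as they stand gave 0.374.

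Calls of the genotype comparison were then set beside those of the supplements in the polyQ line, to see how many went the opposite way. On Rasa-Sindoor 90 rows did, 52 of them lower in PQ_NF than in WT_NF. Among them were sev, Taf12L (14.9 FPKM in PQ_NF, 4.40 in PQ_RS and 2.07 in WT_NF), spok and Obp56d. On Amalaki Rasayana 12 rows did, among them spok, nvd, Obp56d and jhamt, a gene of juvenile hormone synthesis. Since spok and nvd are genes of the ring gland, an organ apart from the disc, the amount of ring gland tissue may differ between groups. This was not tested. Both comparisons use PQ_NF, so a chance deviation there gives opposite ratios without any effect. Simulated unchanged groups gave a mean of 0.30 rows for Rasa-Sindoor and 0.22 for Amalaki Rasayana, and independent lists of these sizes would share 3.73 and 0.357. Part of the excess may come from the shared libraries, and how large that part is was not tested. The trends on transcript length were also opposite: the shortest genes had a median ratio of 0.29 in PQ_NF against WT_NF and −0.38 in PQ_RS against PQ_NF, and the longest −0.09 and 0.14. With both trends removed, an alternative chosen after seeing the data, 45 of the 79 rows for Rasa-Sindoor that could be corrected still passed in both comparisons and 34 did not; with newly passing rows and those that could not be corrected the count was 84. For Amalaki Rasayana 8 of 9 still passed. The covariance of the ratios over 6647 rows was −0.141 for Rasa-Sindoor with −0.0530 simulated, and −0.0579 for Amalaki Rasayana with −0.0531 simulated. Across genes, which are not independent replicates, the correlations were −0.73 and −0.51, with −0.50 simulated in both cases. Against WT_NF, 83 of the 90 rows were not called in PQ_RS, 6 were called the same way as in PQ_NF and 1 the other way. Of the 12 rows, 10 were not called in PQ_AR against WT_NF. A missing call does not show that a level was equal to that of wild type.

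**Figure D2:**
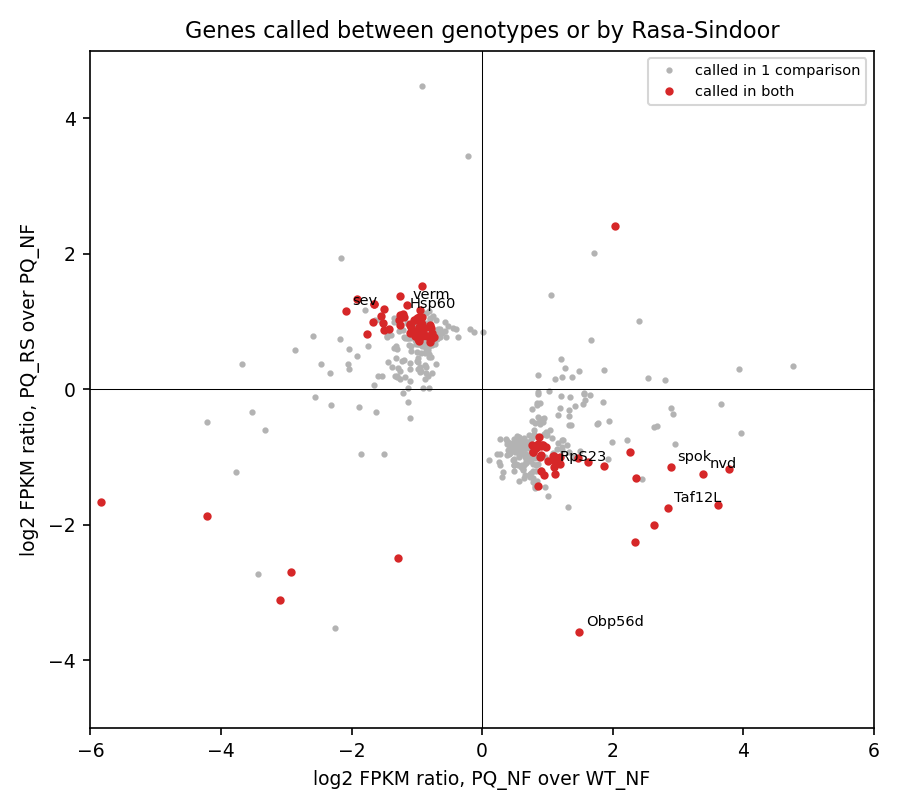
Each point is a gene called in at least 1 of the comparisons, with the log2 FPKM ratio of PQ_NF over WT_NF on the horizontal axis and of PQ_RS over PQ_NF on the vertical axis. Red points are called in both, and 90 of the rows called in both go opposite ways. Both axes contain PQ_NF, which by itself tilts the cloud downwards. Genes listed at 0 in a group are not drawn. The axes are cut, so called rows with larger ratios, such as snRNA:U2:34ABa at −7.41 on the horizontal axis, lie outside the plot.

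Both supplements were called the same way for 18 rows in the polyQ line and 12 in wild type, with simulated means of 0.240 and 0.320 and 0.390 and 0.140 for independent lists. In the polyQ line these included Sgs5, Obp56d, Eig71Ee and spok, and in wild type Sgs7, Sgs5, Sgs3 and Sgs8. The Sgs genes are salivary glue genes, and a difference between groups in salivary gland tissue was not tested. Each pair shares its normal food group, so part of either excess may come from it. The covariances were 0.0776 in the polyQ line with 0.0529 simulated, and 0.00813 in wild type with 0.0545 simulated. The wild-type value lies below its simulation, and whether this comes from the SEs or from supplement effects in opposite directions was not tested. Some list medians were opposite in WT_AR and WT_RS against WT_NF: 0.19 and −0.25 for proteasome subunits and −0.59 and 0.39 for small nuclear and nucleolar RNAs.

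Chromosome-wide levels were examined after the data were seen, over X, 4 and the arms of 2 and 3 in the 9 comparisons. The median ratio of 71 chromosome 4 genes lay above that of chromosome 2 and 3 genes by 0.36 in PQ_NF against WT_NF (90.1% of the genes above), by 0.48 in PQ_AR against WT_AR and by 0.31 in WT_RS against WT_NF, and below it in PQ_RS against PQ_NF, at −0.42. The 1209 X genes lay at −0.17 in PQ_NF against WT_NF, with 7 rows called higher and 63 lower, and at 0.23 in PQ_RS against PQ_NF, with 39 higher and 16 lower. Of the 90 rows called the opposite way by Rasa-Sindoor, 30 lie on X, including sev, and were lower in PQ_NF than in WT_NF.

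**Figure D3:**
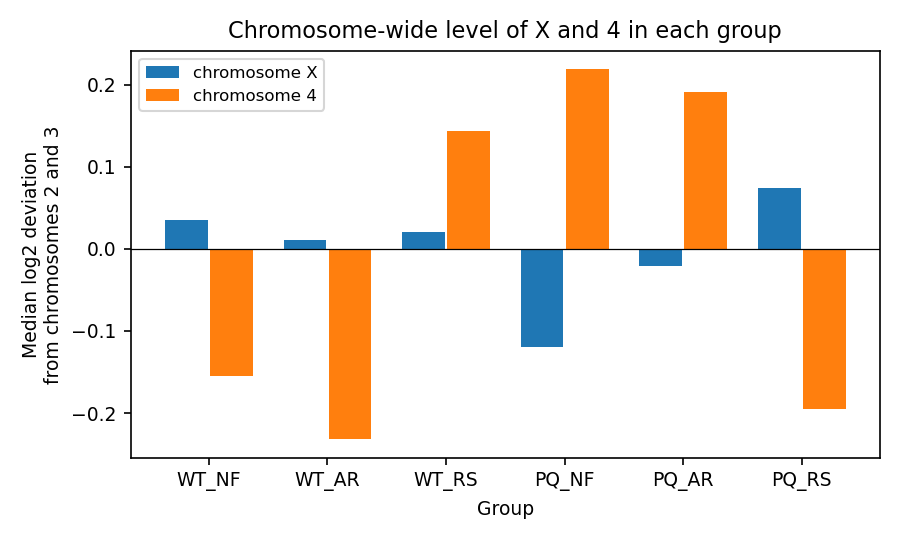
Bars give, for each group, the median log2 deviation of the genes of chromosome X (1209 genes) and of chromosome 4 (71 genes) from their mean over the 6 groups, minus that of chromosome 2 and 3 genes; there is 1 pooled value per group and no error bar. Chromosome 4 lies at 0.22 in PQ_NF, 0.19 in PQ_AR and 0.14 in WT_RS and between −0.16 and −0.23 in the other 3 groups, and X is lowest in PQ_NF at −0.12.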

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

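The results in this part passed the test of a difference between the genotypes in a supplement's effect. The rule for contradictory rows was chosen only after the results were seen.

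For Amalaki Rasayana the effect in the polyQ line minus that in wild type was −4.59 on the log2 scale for Hsp70Bb and −3.69 for Hsp68. Both genes rose in wild type, Hsp68 from 3.12 to 62.5 FPKM, while in the polyQ line Hsp68 went from 9.95 to 15.5 and Hsp70Bb from 5.86 to 6.93. The polyQ line on normal food already lay above wild type for both, and its level on the supplement stayed below that of WT_AR. Hsp70Bc, a near-identical copy of Hsp70Bb, had only 0.457 FPKM in PQ_NF and 0.893 in PQ_AR, with 5.99 in WT_AR. Its difference of −3.35 (SE 1.06) went the same way but did not pass. How reads were split between these copies is uncertain, so the Hsp70Bb levels in the polyQ line and its difference are uncertain too. In wild type the list of chaperones moved with Hsp68 and Hsp70Bb (7 of 24 called higher), and no technical explanation was tested.

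The other differences for Amalaki Rasayana were 1.74 for snoRNA:Me18S-U1356a, 2.09 for snoRNA:Me28S-A774b, 2.22 for snoRNA:Me28S-A2634a and 2.48 for mir-1006. For Rasa-Sindoor they were −3.56 for snoRNA:Me28S-A771, −2.19 for snoRNA:Me28S-G3277a, −1.75 for snoRNA:Me18S-G1620, −0.78 for snoRNA:Me18S-A1806, 0.26 for mir-305 and 1.08 for mir-2283. In each of these 10 rows, in at least 1 of the comparisons used, the statistic in the authors' deposited table is beyond 3 in size while the p beside it is above 0.05. The row that joins CG3860 with mir-1009 differed by −9.63, with 1332 FPKM in WT_RS and between 2.22 and 3.40 in PQ_RS, PQ_NF and WT_NF. Such short RNAs hold few possible fragment positions, and the FPKM of a row that joins a gene with a microRNA cannot be assigned to either. With rescaled SEs and without contradictory rows, 16 rows passed for Amalaki Rasayana (3 with the polyQ effect above, 13 below) and 80 for Rasa-Sindoor (61 above, 19 below).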

How the results depend on the processing

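No paired analysis was possible because the table holds 1 pooled value per group. For the same reason no library could be left out and no other split of the libraries could be tested, so nothing here shows whether a single library decides a value. Centring on the median shifts all genes alike by too little to turn a called change and cannot move a percentile, so it is left out of these tallies. Of 138 other alternatives to the 24 counts, 90 stayed within 1.5 times the reported count, 44 fell below and 4 rose above. Stricter thresholds keep fewer genes by construction.

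With a q of at most 0.01, higher and lower calls were 70 and 116 in PQ_NF against WT_NF, 37 and 79 in PQ_RS against PQ_NF, 12 and 32 in WT_AR against WT_NF, 9 and 12 in WT_RS against WT_NF, 12 and 14 in PQ_RS against PQ_AR, 42 and 53 in WT_RS against WT_AR, and 62 and 60 in PQ_AR against WT_AR. PQ_AR against PQ_NF had 0 higher, and PQ_RS against WT_RS 47 lower. With a change of at least 1 on the log2(FPKM + 1) scale the counts were, in the same order, 71 and 69, 14 and 59, 11 and 26, 11 lower for WT_RS against WT_NF, 11 and 12, 33 and 34, and 41 and 48, with 0 higher for PQ_AR against PQ_NF and 41 and 40 for PQ_RS against WT_RS. Adjusted within the comparison, PQ_AR against PQ_NF had 0 higher, WT_AR against WT_NF 42 lower, WT_RS against WT_NF 8 higher and 12 lower, and PQ_RS against PQ_AR 19 lower. With single named genes WT_RS against WT_NF had 10 higher. The rows called the opposite way were 5 (q) and 7 (change) for Amalaki Rasayana and 35 and 18 for Rasa-Sindoor, and those called the same way by both supplements in the polyQ line 10 and 10. The tests of a difference between genotypes, with alternatives chosen after seeing the data, gave 22 and 97 with rescaled SEs and 16 and 80 without contradictory rows.

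With the length trend removed, also chosen after seeing the data, PQ_RS against PQ_NF had 92 higher and 121 lower, which are partly other genes. Of 1139 alternatives to list medians, 1058 kept their side of the percentile bounds, 47 no longer stood apart and 34 newly did. Matching on transcript length as well, chosen after seeing the data and drawn from another pool of rows, made 16 and 14 of these changes. Named genes' log2 ratios were tried with other pseudocounts and centring alone, which cannot turn a called change, so their direction was not tested.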

Other observations

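The tests of expression of the polyQ protein, of exchanged labels and of copy number were chosen only after the results were seen, as were the pattern of chromosome 4, the split of kept and lost calls and the interval of the ribosomal protein median.

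Replication-dependent histone genes, of which 7 were tested and which share reads among near-identical copies, had a median of 0.46 in PQ_AR against WT_AR and −0.34 in PQ_RS against PQ_NF on the log2(FPKM + 1) scale, with no member called; the latter lay at the percentile 1.16 of lists matched on expression but at 4.46 when matched on length as well. Small nuclear and nucleolar RNAs had a median of 0.96 in WT_RS against WT_AR (9 of 274 called higher) and −0.42 in PQ_RS against WT_RS. Haemocyte markers lay lower than matched lists in both WT_AR and WT_RS against WT_NF (medians −0.27 and −0.18, with 2 and 1 of 10 called lower).

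Short genes were prominent among those lower on Rasa-Sindoor in the polyQ line. The 747 genes with the shortest transcripts had a median log2 ratio of −0.38 and the 746 with the longest 0.14. After the length trend was removed, 52.5% of the called genes that could be corrected (117 of 223) were still called by the z bound. This lay between the bounds of 50% and 80% set beforehand. The lower genes went from a median of −0.97 to −0.79 with a median rescaled SE of 0.24. The 79 lower genes that lost their call had a median transcript of 747 bases and a median trend of 0.34 removed, which took their median ratio from −0.96 to −0.68; the 64 that kept it had 1430 bases, a trend of 0.10 and a median ratio of −0.94 after the correction. Among lower genes the lost calls were thus mostly of short transcripts with a larger correction, so a length bias of the libraries may account for part of the pattern, and it cannot be told apart from a change of short genes. In these pooled values the ribosomal protein genes did not fall more than other genes of like length and expression. Such a fall needs a median below that of matched lists, which ranged from −0.55 to −0.29. The median of 75 genes was −0.36 (95% bootstrap interval −0.49 to −0.18), at the percentile 83.7. Matched genes may have fallen for a shared reason, so a fall of short genes that includes these is not excluded. That percentile missed the bound of 25 to 75 set beforehand on the side away from a fall, and the interval was added after the percentile was seen. The interval resamples genes and does not measure the spread between libraries.

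The 52 rows that differ between the genotypes on all 3 foods are a candidate for strain background. They held 5 pairs of neighbouring rows, against a mean of 0.269 and a maximum of 3 in random draws. Stretches of the genome that differ between the strains would give such pairs. The draws took rows singly, so a single missing stretch or gene cluster counts as several pairs. Rows without a neighbour among the 52 are not covered by this test. Expression of the polyQ protein stays open: 0 of the 48 tested members of the eye lists were among them, but chance alone would give 0.247, so the test had no power to exclude it. The design gives no control with the background of the polyQ line and without the protein.

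Chromosome 4 genes were higher in PQ_NF, PQ_AR and WT_RS than in the other 3 groups. Their median change between PQ_NF and WT_NF of 0.39 lay at the percentile 100 of lists matched on transcript length and expression, whose upper bound was 0.12, which argues against length bias. An exchange of the labels of the 2 Rasa-Sindoor groups was tested on 126 genes called the same way on the other 2 foods: 88.1% (111; exact 95% interval 81.1 to 93.2) lay the same way between PQ_RS and WT_RS and 15 the other way. That missed the bound of 90% written for this test. A complete exchange would need over 90% the other way, so it is excluded. An exchange of single libraries would give each Rasa-Sindoor group part of the other's level. Spn47C had 7.38 FPKM in PQ_RS and 0.459 in WT_RS, nAChRalpha6 4.04 and 0.158, and CG33766 0 and 4.74. Each group thus held the level of its own genotype, which argues against an exchanged library for these genes. They were picked from the 52 rows called on all 3 foods, Rasa-Sindoor included. A smaller admixture was not tested. Another copy number of chromosome 4 may be a cause and cannot be excluded or shown: in 8 of 9 combinations of 3 segments of the chromosome with 3 comparisons over 90% of genes lay above the chromosome 2 and 3 median, and the lowest share was 87.0%. A biological effect of the supplements on chromosome 4 was not tested.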
